A study of Mus musculus with 3 samples.

How the data were processed

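The study measured gene expression by RNA sequencing in lung homogenates of female BALB/c mice. Per the labels' protocols, total RNA was extracted with Trizol, 1.3 µg went into each library, and libraries were made with a strand-preserving kit (NEBNext Ultra II Directional). Per the labels, PM10 was given in 20 µL of saline, OVA mice were sensitised by intraperitoneal injection of 20 µg OVA with aluminium hydroxide, the last time on day 14, and challenged intranasally with 30 µL of a solution of 1 mg/mL on days 21, 22 and 23, and tissue was taken 2 days after the last challenge. The 3 libraries (control, PM10 and OVA+PM10) were assigned to their groups by their titles, with 1 library in each of the groups.

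The deposited values were FPKM (fragments, or possibly reads, per kilobase of transcript and per 1000000 mapped) for 23183 genes per library, a unit inferred from the values themselves since no header names it. Per the submitters' processing notes, TopHat and the mouse genome build mm10 were used. The program that counted reads, the annotation, the use of strand and the handling of reads matching several places are not given in the sources used here, so that values of near-identical paralogs, pseudogenes and overlapping or antisense genes are uncertain. Mitochondrially encoded genes had no values. No further scaling was applied. The summed FPKM was 546315 in the control library, 1293180 in the PM10 library and 855739 in the OVA+PM10 library, and 5683, 6942 and 6390 genes were listed at 0. A value of 0 can be a failed estimate: Tgoln2, a gene used by most cells, was listed at 0 in the PM10 library and exceeded 20 FPKM in both others. Such genes are therefore described as listed at 0, with no fold.

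Depth was estimated from the lowest values. In genes with a single annotated transcript, FPKM multiplied by transcript length clustered at the value of 1 read, which was 49.6 in the control library, 76.3 in the PM10 library and 65.9 in the OVA+PM10 library. These values correspond to about 20.1, 13.1 and 15.2 times 1000000 reads and to 0.0496, 0.0763 and 0.0659 FPKM for 1 read in a transcript of 1 kilobase, so that values below about 1 FPKM rest on few reads. They are approximate, since the authors' gene lengths are not known. Reads were rebuilt from them only for histone genes, as a check on their level, and no counting intervals are given.

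For each pair of libraries, a log2 ratio of FPKM + 1 was computed, which understates the change of genes with low values. Genes were counted as at least 2-fold higher or lower when they had at least 1 FPKM in the higher library. Because each group had 1 library, no test between groups was possible and no p-value, standard error or left-out replicate could be given. Before the data were examined, 42 gene lists (cell type markers, pathways and tissues a dissection could include) were fixed. For the 40 with at least 5 members at 1 FPKM or more in any library, the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression, with a list standing apart below the percentile of 2.5 or above 97.5. Such percentiles describe these libraries and are not tests of the treatments. The plan had foreseen counts with a composition-adjusted scaling, and gave the log2 ratio of value + 1 for the case of FPKM, which was used here. Named genes were the 10 with the highest and the 10 with the lowest ratio in each comparison among genes with at least 5 FPKM in the higher library, leaving out predicted genes, up to 4 members per list with the largest ratios (6 for a list that stood apart), and a fixed set of genes of type 2 inflammation, particle response and lung cell types. The genes Rmrp and Tgoln2, named in the text, lay outside this rule and were chosen after their values had been seen.

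Alternatives were another pseudocount (0.25 or 5 FPKM), no filter or a filter at 5 FPKM, thresholds of 4-fold and 1.5-fold, scaling by the median ratio to a mean library, scaling to the same sum of 1000000, and leaving out hemoglobin, immunoglobulin and cardiac muscle genes with rescaling. The 3 further ones were chosen after seeing the data: removal of the trend over transcript length (a running median over genes ordered by length), random lists matched on 10 bins of expression and 10 of length, and counts without squamous epithelium and skeletal muscle genes. Transcript length (the longest transcript) and coordinates came from GENCODE M21 on GRCm38, the assembly that mm10 names, matched by symbol for 22148 genes, or 95.5%. The overlap of calls against the shared control library was set against 100 simulated trios of unchanged libraries. Their spread was taken from the ratios between the 2 exposed libraries, which hold real differences too. Those log2 ratios had a standard deviation of 0.90, against 1.17 (PM10) and 0.996 (OVA+PM10) for the ratios to control. The spread may therefore be too small for the control library.

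The code was tested on simulated data, in which 200 of 23183 genes of a copy of the control library were changed 4-fold and a length trend was added. With 1 read-sampled library against another, 97% of the raised and 100% of the lowered genes came out at least 2-fold changed, and removal of the trend reduced the difference between the shortest and the longest of 10 classes of unchanged genes from 1.44 to 0.083 on the log2 scale. Of 200 random lists, 7.0% stood apart. Of 50 lists of short genes, 100% stood apart with matching on expression and 12.0% with matching on length too, so that length matching removed most but not all of such a trend. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.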

Results

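RNA from lung homogenates of female BALB/c mice, whose age is given as 10 weeks in one label and as 5 to 6 weeks in another, was sequenced in 3 libraries with 1 library per group. The control library came from mice labelled control, with no vehicle named, the PM10 library from mice given particulate matter (a certified fine-dust reference material with particles up to the PM10 size class) into the nose 4 times over 2 weeks, and the OVA+PM10 library from mice that received the same particles and were also made allergic to ovalbumin (OVA, an egg-white protein commonly used to model allergic asthma). The labels give 5 mice per group and particle doses of 100 or 200 µg, and state neither which dose was sequenced nor whether a library held RNA from 1 mouse or from several. Each library had a value for 23183 genes. The smallest steps between low values implied about 20.1, 13.1 and 15.2 times 1000000 reads in the control, PM10 and OVA+PM10 libraries. With 1 library per group, none of the differences below had a replicate check, no p-value was computed, and each ratio compares libraries and not conditions. No library of mice given OVA alone was among those analysed here, so that the part of OVA and the part of the particles in the OVA+PM10 library could not be separated.

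Directions below are relative to the median gene, whose log2 ratio lay near 0 in every comparison (0.02 for PM10 against control, -0.0017 for OVA+PM10 against control and -0.03 for OVA+PM10 against PM10). Scaling the libraries to the same summed FPKM would shift these ratios by about -1.24, -0.65 and 0.60 on the log2 scale, and a gene or group whose ratio has the opposite sign to that shift and is smaller in size lies on the other side of 0 on that scale. A gene list is said to stand apart when its median log2 ratio lay outside the central 95% of 10000 random lists matched on expression. About 2 of the 40 lists with at least 5 measured members would lie outside that range in each comparison if genes varied independently. Genes of the same cell type or of similar transcript length can vary together between any 2 libraries, so more lists can then lie outside it. How many would do so between unchanged libraries was not tested.

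The first comparison asked how the lung transcriptome of mice given PM10 differed from that of control mice. The gene with the highest ratio was the ribosomal RNA precursor Rn45s, at 8570 FPKM in the PM10 library and listed at 0 in both others. The small non-coding RNAs Rprl3 (53.0 FPKM), Bc1 (43.6 FPKM), both listed at 0 in the control library, and Rpph1 (71.7 against 2.54 FPKM) were also among the 10 named for the highest ratios. Among protein-coding genes, some that macrophages express were far higher in the PM10 library, although whether the markers of recruited macrophages stood apart as a list depended on the treatment of transcript length. Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499, mm10), stood at 136 FPKM in the PM10 library and 1.30 FPKM in the control library, a log2 ratio of 5.89. Trem2, a lipid receptor of macrophages (chromosome 17, 48346401 to 48354147), stood at 56.5 against 3.05 FPKM, and Gpnmb, a glycoprotein of lipid-laden macrophages (chromosome 6, 49036546 to 49070929), at 76.3 against 4.54 FPKM. Ctsk, which encodes the protease cathepsin K, had 207 FPKM in the PM10 library and 18.1 FPKM in the control library, and Clec4d, a pattern recognition receptor of myeloid cells, 65.8 and 2.42 FPKM. Of 24 measured markers of monocytes and recruited or interstitial macrophages, 10 were at least 2-fold higher and 2 at least 2-fold lower in the PM10 library, but the list's median of 0.78 lay at the percentile of 93.9 and did not stand apart, whereas with the trend over transcript length removed it did (9 higher and 2 lower, median 0.62, percentile 99.5). Of 22 alveolar macrophage markers, 7 were higher and 2 lower, with a median of 0.78 at the percentile of 98.0, or 96.3 among random lists matched on transcript length as well. Atp6v0d2 (107 against 18.9 FPKM) and Krt79 (34.5 against 3.68 FPKM) were higher, whereas Fabp4, a fatty-acid-binding protein that adipose tissue also expresses, was lower (40.9 against 118 FPKM).

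Several cytokine and chemokine genes of innate inflammation were also higher. Among 32 measured proinflammatory genes, 14 were at least 2-fold higher and 3 lower in the PM10 library, with a median log2 ratio of 0.68 at the percentile of 100. With the length trend removed, 12 were higher and 5 lower, the median was 0.19, and the list no longer stood apart (percentile 97.1). Among random lists matched on length too it did (percentile 99.6). The neutrophil-attracting chemokine Cxcl3 had 16.7 FPKM in the PM10 library and 0.269 FPKM in the control library. Ccl3, which attracts monocytes, had 26.6 and 1.503 FPKM, Ccl20, the ligand of CCR6, 6.53 and 0.074 FPKM, and Il1b, which encodes interleukin-1β, 25.2 and 6.27 FPKM. Il6 and Tnf were low in both libraries, at 1.315 and 1.46 FPKM in the PM10 library and 0.099 and 0.419 FPKM in the control library. Ccl17, a chemokine of dendritic cells and macrophages that attracts CCR4-bearing T cells, had the log2 ratio of 4.37, with 203 FPKM in the PM10 library and 8.84 FPKM in the control library. The acute phase proteins Saa3 (115 against 7.68 FPKM) and Lcn2 (808 against 106 FPKM) were higher, while the acute phase and complement list as a whole, with 7 of 20 members higher and 2 lower, lay at the percentile of 76.0.

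Some markers of NK cells and T cells were higher, and the call for NK cells depended on how transcript length was handled. Of 14 markers of natural killer (NK) and cytotoxic cells, 8 were at least 2-fold higher and 1 was lower in the PM10 library, with a median log2 ratio of 1.12 at the percentile of 100. With the length trend removed, 1 was higher and 1 lower, the median was 0.25, and the list no longer stood apart (percentile 91.7). Among random lists matched on length too it did (percentile 99.2). Granzyme A, Gzma, had 374 FPKM in the PM10 library and 82.8 FPKM in the control library, and the NK receptor chain Klrd1 13.2 and 4.05 FPKM, while perforin, Prf1, had 1.22 and 5.56 FPKM. Of 26 T cell markers, 4 were higher and 2 lower, with a median of 0.45 at the percentile of 99.9. Chains of the T cell receptor complex went both ways, with Cd3d at 46.9 against 9.04 FPKM and Cd3e at 4.76 against 11.9 FPKM. Of 22 B cell and plasma cell markers, 3 were higher and 1 was lower (median -0.04, percentile 29.0). All 36 cytosolic ribosomal protein genes were at least 2-fold higher in the PM10 library, with a median of 2.08 against 1.13 for matched random lists. Their transcripts are short, and with the length trend removed 23 were higher and the median was 1.27. Ribosomal protein genes made up 35.3% of the summed FPKM in the PM10 library, 15.5% in the control library and 25.6% in the OVA+PM10 library.

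Particle-response genes did not move as one group. Cyp1a1, the monooxygenase induced through the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824), stood at 7.21 FPKM in the PM10 library and 2.25 FPKM in the control library. It was the single member at least 2-fold higher among 16 measured targets of that receptor, of which 6 were at least 2-fold lower, with a median log2 ratio of -0.86 at the percentile of 0.25. Aldh3a1 (0.735 against 20.1 FPKM) and Ugt1a6a (0.475 against 9.43 FPKM) were lower, and Cyp1b1 had 1.15 and 2.77 FPKM. The oxidative stress genes controlled by NRF2 had a median of 0.10, with 8 of 35 members at least 2-fold higher and 1 lower, at the percentile of 3.30. Among random lists matched on length this list stood apart as lower (percentile 0.63), and with the length trend removed 5 members were higher and 5 lower. Hmox1 (31.1 against 22.0 FPKM) and Nqo1 (4.25 against 8.08 FPKM) stayed within 2-fold, as did the metallothioneins Mt1 (215 against 108 FPKM) and Mt2 (94.5 against 137 FPKM). For the metal response list, 3 of 19 members were higher and none was lower.

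Some genes of airway secretory cells and of the connective tissue were lower in the PM10 library, while some of those of ciliated airway cells were higher. Of 39 ciliated cell and axoneme genes, 12 were at least 2-fold higher and 1 was lower (median 0.44), at the percentile of 99.2, or 94.1 with matching on length and 100 with the length trend removed. Rsph1, a radial spoke protein of cilia, had 56.8 FPKM in the PM10 library and 14.3 FPKM in the control library. The other 26 genes stayed within 2-fold, among them Foxj1 (16.5 against 13.6 FPKM) and Dnah5 (1.44 against 1.82 FPKM). Of 25 club and secretory cell markers, 9 were at least 2-fold lower and 2 higher, with a median of -0.29 at the percentile of 0.01. Bpifb1, a secreted airway protein, had 0.619 FPKM in the PM10 library and 32.1 FPKM in the control library, and the antimicrobial lectin Reg3g 1.20 and 41.5 FPKM, whereas Scgb1a1, the main club cell secretory protein, was among the most abundant transcripts of both (50391 and 42979 FPKM). Of 36 fibroblast and extracellular matrix genes, 12 were lower and 6 higher (median -0.51, or -0.24 with the length trend removed), and the proteoglycan genes Dcn (8.40 against 246 FPKM) and Lum (1.38 against 38.6 FPKM) had the lowest ratios among them. Of 20 smooth muscle and pericyte genes, 9 were lower and 1 higher (median -0.96, or -0.53 with the length trend removed), including smooth muscle myosin, Myh11 (8.37 against 42.1 FPKM). Of 17 alveolar type 1 cell markers, 7 were lower and 1 higher, with a median of -0.26 against 0.68 for matched random lists.

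Genes of other tissues that were present in the control library were lower as well. All 16 measured skeletal muscle genes were at least 2-fold lower in the PM10 library (median -5.99), as were 19 of 24 cardiac muscle genes and 12 of 16 adipose tissue genes. Skeletal muscle actin, Acta1 (chromosome 8, 123891769 to 123894751), had 966 FPKM in the control library and was listed at 0 in the PM10 library, and Car3, an abundant carbonic anhydrase of adipose tissue and muscle, had 168 and 0.206 FPKM. Keratins and other genes of stratified squamous epithelium were among those with the lowest ratios. Krt13 (chromosome 11, 100117327 to 100121566) had 2574 FPKM in the control library and was listed at 0 in the PM10 library, and Krt4 had 1171 and 0.212 FPKM. Chil4, a chitinase-like gene with a near-identical neighbour, Chil3, had 3160 FPKM in the control library and 0.104 FPKM in the PM10 library, while Chil3 had 93.4 and 641 FPKM. The handling of reads that match both genes is not given in the sources used here, and their sum was 3253 and 641 FPKM.

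In all, 1869 genes were at least 2-fold higher and 1907 at least 2-fold lower in the PM10 library than in the control library, among 13693 genes with at least 1 FPKM in either. The split was 262 higher and 7392 lower after scaling to the same sum, 1267 and 749 with 5 FPKM added to each value in place of 1, and 303 and 525 at a 4-fold threshold. Ratios also followed transcript length: among 10 equal classes, the genes with the shortest transcripts (121 to 1289 bases) had a median log2 ratio of 1.10, and those with the longest (6630 bases or more) one of -0.77. With this trend removed, an alternative chosen after seeing the data, 1017 genes were higher and 1486 lower, and the alveolar macrophage list (percentile 77.0) and the endothelial list (9.47), like the proinflammatory and NK lists, no longer stood apart. The interferon, NRF2, junction, eosinophil and mast cell lists then stood apart as lower, which they did not with the trend left in and matching on expression alone. Of the 6 lists that stood apart as higher and the 11 as lower, 4 and 10 also did so among random lists matched on length.

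**Figure D1:**
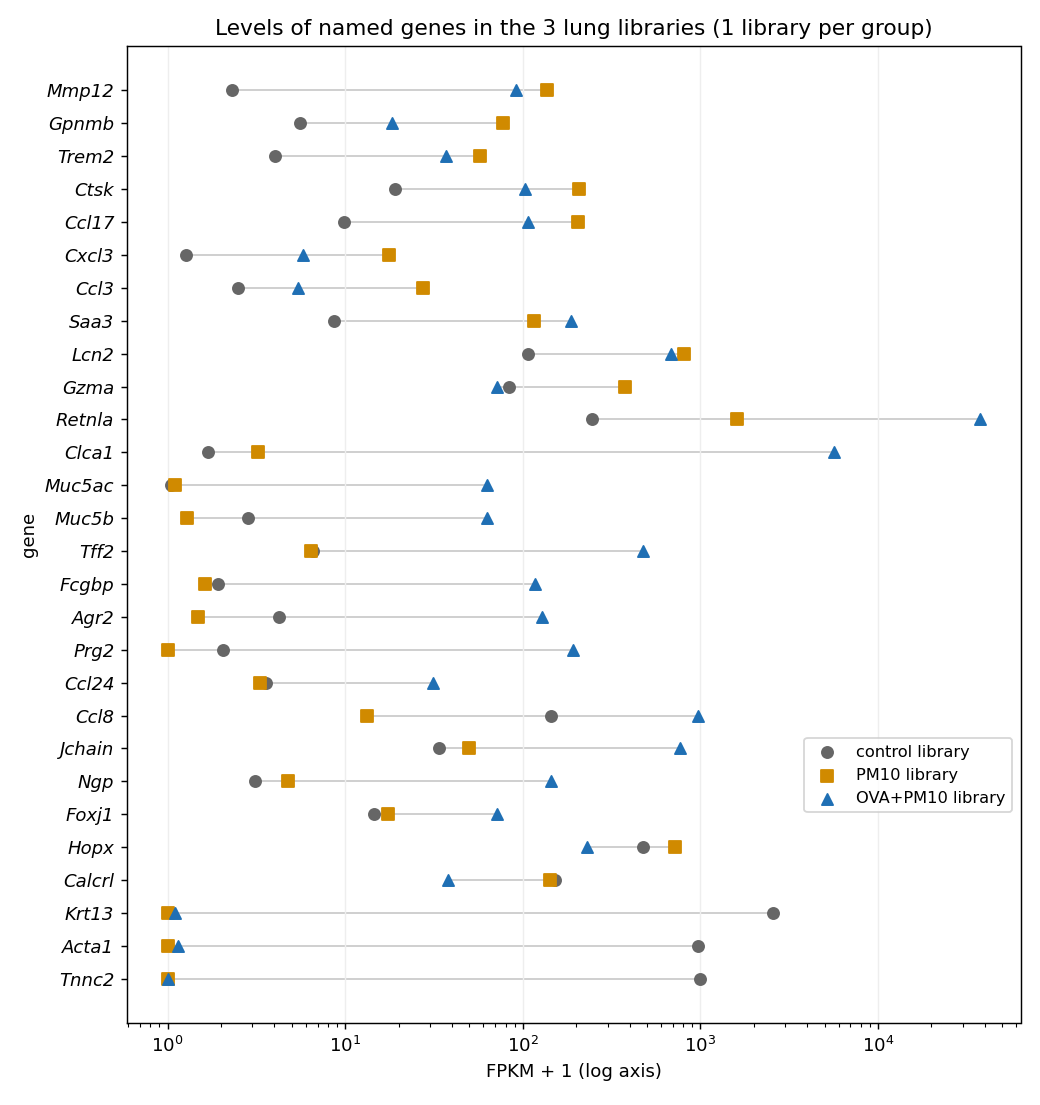
Levels of 28 genes in the control library (circles), the PM10 library (squares) and the OVA+PM10 library (triangles), as FPKM + 1 on a log axis, with 1 library per group and a line spanning the 3 values. Mmp12 lies at 136 FPKM in the PM10 library against 1.30 in the control library, Clca1 at 5628 FPKM in the OVA+PM10 library against 0.695 in the control library, and Krt13 at 2574 FPKM in the control library alone.

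The comparison of the OVA+PM10 library with the control library asked how lungs exposed to both the allergen and the particles differed from control lungs. Genes of mucous secretory cells and of the response to interleukin-13 (IL-13) were among those with the highest ratios. Clca1, a secreted mucus-associated metalloprotease and regulator of chloride channels (chromosome 3, 145003817 to 145032776), had 5628 FPKM in the OVA+PM10 library and 0.695 FPKM in the control library, a log2 ratio of 11.70. Retnla, a resistin-like protein of alternatively activated macrophages and airway epithelium (chromosome 16, 48842551 to 48844461), had 37463 and 245 FPKM. The mucin genes Muc5ac (chromosome 7, 141788972 to 141819231) and Muc5b stood at 61.8 and 61.5 FPKM against 0.052 and 1.84 FPKM. Of 25 measured IL-13-responsive genes, 20 were at least 2-fold higher and 1 was lower, with a median log2 ratio of 3.38, and of 26 mucins and mucus-associated genes, 18 were higher and 3 lower, with a median of 2.16. Other members included the trefoil factor Tff2 (477 against 5.60 FPKM), the mucus protein Fcgbp (116 against 0.912 FPKM), the disulfide isomerase Agr2 (127 against 3.25 FPKM), the lectin Itln1 (61.7 against 0.233 FPKM) and the anion exchanger Slc26a4 (43.8 against 0.374 FPKM). The IL-13-responsive and mucin lists are not separate, since both hold Clca1, Muc5ac, Tff2, Fcgbp, Agr2, Itln1 and Slc26a4. The single lower member of the IL-13-responsive list was Chil4 (602 against 3160 FPKM), while Chil3 stood at 2106 against 93.4 FPKM. Summed, the pair had 2707 and 3253 FPKM, and the control sum rested mostly on Chil4. Whether reads were divided correctly between these genes, or whether Chil4 in the control library came from another tissue, was not tested.

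Of the type 2 cytokines, Il4 and Il13 were low but at least 2-fold higher than in the control library by the log2 ratio used here, and Il5 was not. Il4 had 4.28 FPKM in the OVA+PM10 library and 0.223 FPKM in the control library, Il13 2.13 and 0.130 FPKM, and Il5 1.07 and 0.163 FPKM. Il33, an epithelial alarmin, had 61.3 and 33.6 FPKM, and Tslp, another, 1.15 and 2.25 FPKM. The eotaxin Ccl24 had 30.3 and 2.57 FPKM, Ccl8 972 and 143 FPKM, and Ccl11 95.2 and 50.04 FPKM. Of 20 genes in the type 2 list, 9 were at least 2-fold higher and none was lower, with a median of 0.90 at the percentile of 99.99. Of 13 eosinophil markers, 8 were higher and none was lower, with a median of 1.12 at the percentile of 100. The type 2 and eosinophil lists are not separate either, since both hold Ccr3. Prg2, the eosinophil major basic protein (chromosome 2, 84980461 to 84983632), stood at 191 against 1.04 FPKM and the eotaxin receptor Ccr3 at 7.86 against 1.59 FPKM, whereas Siglecf, which alveolar macrophages share, stood at 7.86 against 6.38 FPKM. The eosinophil-associated ribonuclease genes Ear6 (47.2 against 2.60 FPKM) and Rnase2a (489 against 16.0 FPKM) belong to a family of near-identical copies, and their separate values are uncertain.

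Neutrophil, plasma cell, recruited macrophage and proliferation genes were higher as well. Of 17 neutrophil markers, 11 were at least 2-fold higher and 1 was lower (median 1.15), among them the granule genes Ngp (142 against 2.10 FPKM) and Camp (112 against 1.92 FPKM) and the calprotectin chain S100a8 (1958 against 494 FPKM). Of 22 B cell and plasma cell markers, 9 were higher and none was lower (median 0.88). The joining chain of secreted antibodies, Jchain, had 766 and 32.8 FPKM, and Mzb1, a chaperone of plasma cells, 420 and 8.62 FPKM. Of 24 monocyte and recruited macrophage markers, 11 were higher and none was lower (median 0.91), with Mmp12 at 90.9 against 1.30 FPKM and the complement component C1qb at 207 against 59.4 FPKM. Alveolar macrophage markers were not higher as a list (5 of 22 higher and 5 lower, median 0.17, percentile 60.8), and Marco stood at 1.16 against 7.36 FPKM. Arg1, the arginase of alternatively activated macrophages, stood at 48.8 against 5.12 FPKM. Of 35 cell cycle genes, 24 were higher and none was lower (median 1.30), including Mki67 (16.8 against 3.47 FPKM) and Birc5 (26.1 against 3.15 FPKM). The acute phase and complement list had 13 of 20 members higher and 1 lower (median 1.37), with Saa3 at 185 against 7.68 FPKM and the polymeric immunoglobulin receptor Pigr at 342 against 18.9 FPKM. These lists lay at the percentile of 100 with matching on expression and above 99.9 with matching on length too.

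Among structural cells, markers of airway epithelium were higher and markers of the gas-exchange surface lower. Of 39 ciliated cell and axoneme genes, 34 were at least 2-fold higher and none was lower, with a median log2 ratio of 1.69. Foxj1, the transcription factor of motile cilia, had 70.6 FPKM in the OVA+PM10 library and 13.6 FPKM in the control library, and the dynein heavy chain Dnah5 8.99 and 1.82 FPKM. Of 25 club and secretory cell markers, 13 were higher and 2 lower (median 1.00, or 0.61 with the length trend removed), with Reg3g at 330 against 41.5 FPKM and Bpifa1 at 18.7 against 283 FPKM. Of 17 alveolar type 1 cell markers, 13 were lower and none was higher (median -1.58), such as Hopx (230 against 472 FPKM; chromosome 5, 77086988 to 77115121) and Akap5 (10.95 against 76.9 FPKM). Of 23 endothelial markers, 13 were lower and none was higher (median -1.08), such as the angiopoietin receptor Tek (25.5 against 110 FPKM) and the adrenomedullin receptor Calcrl (37.1 against 151 FPKM). Alveolar type 2 cell markers had a median of -0.07, with 3 of 19 higher and 2 lower, at the percentile of 0.99, or 8.96 with matching on length and 28.9 with the length trend removed. Sftpc, surfactant protein C, had 24439 and 22645 FPKM.

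Squamous epithelium and skeletal muscle genes of the control library were far lower in the OVA+PM10 library too. All 16 skeletal muscle genes, 15 of 24 cardiac muscle genes and 9 of 16 adipose tissue genes were at least 2-fold lower, and Krt13 stood at 0.107 against 2574 FPKM. The 2 muscle lists are not separate, since both hold Ckm (8.35 against 612 FPKM). Another 9 cardiac muscle genes stayed within 2-fold, among them Actc1 (60.4 against 48.4 FPKM). Fibroblast and smooth muscle lists did not stand apart in this comparison (percentiles 68.2 and 12.5). In all, 1381 genes were at least 2-fold higher and 1204 at least 2-fold lower among 13877. Scaling to the same sum gave 652 and 3560, and 5 FPKM added gave 694 and 524. The class of genes with the shortest transcripts had a median log2 ratio of 0.60 and that with the longest one of -0.36. Of the 19 lists that stood apart as higher and the 8 as lower, 17 and 7 also did so among random lists matched on length.

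**Figure D2:**
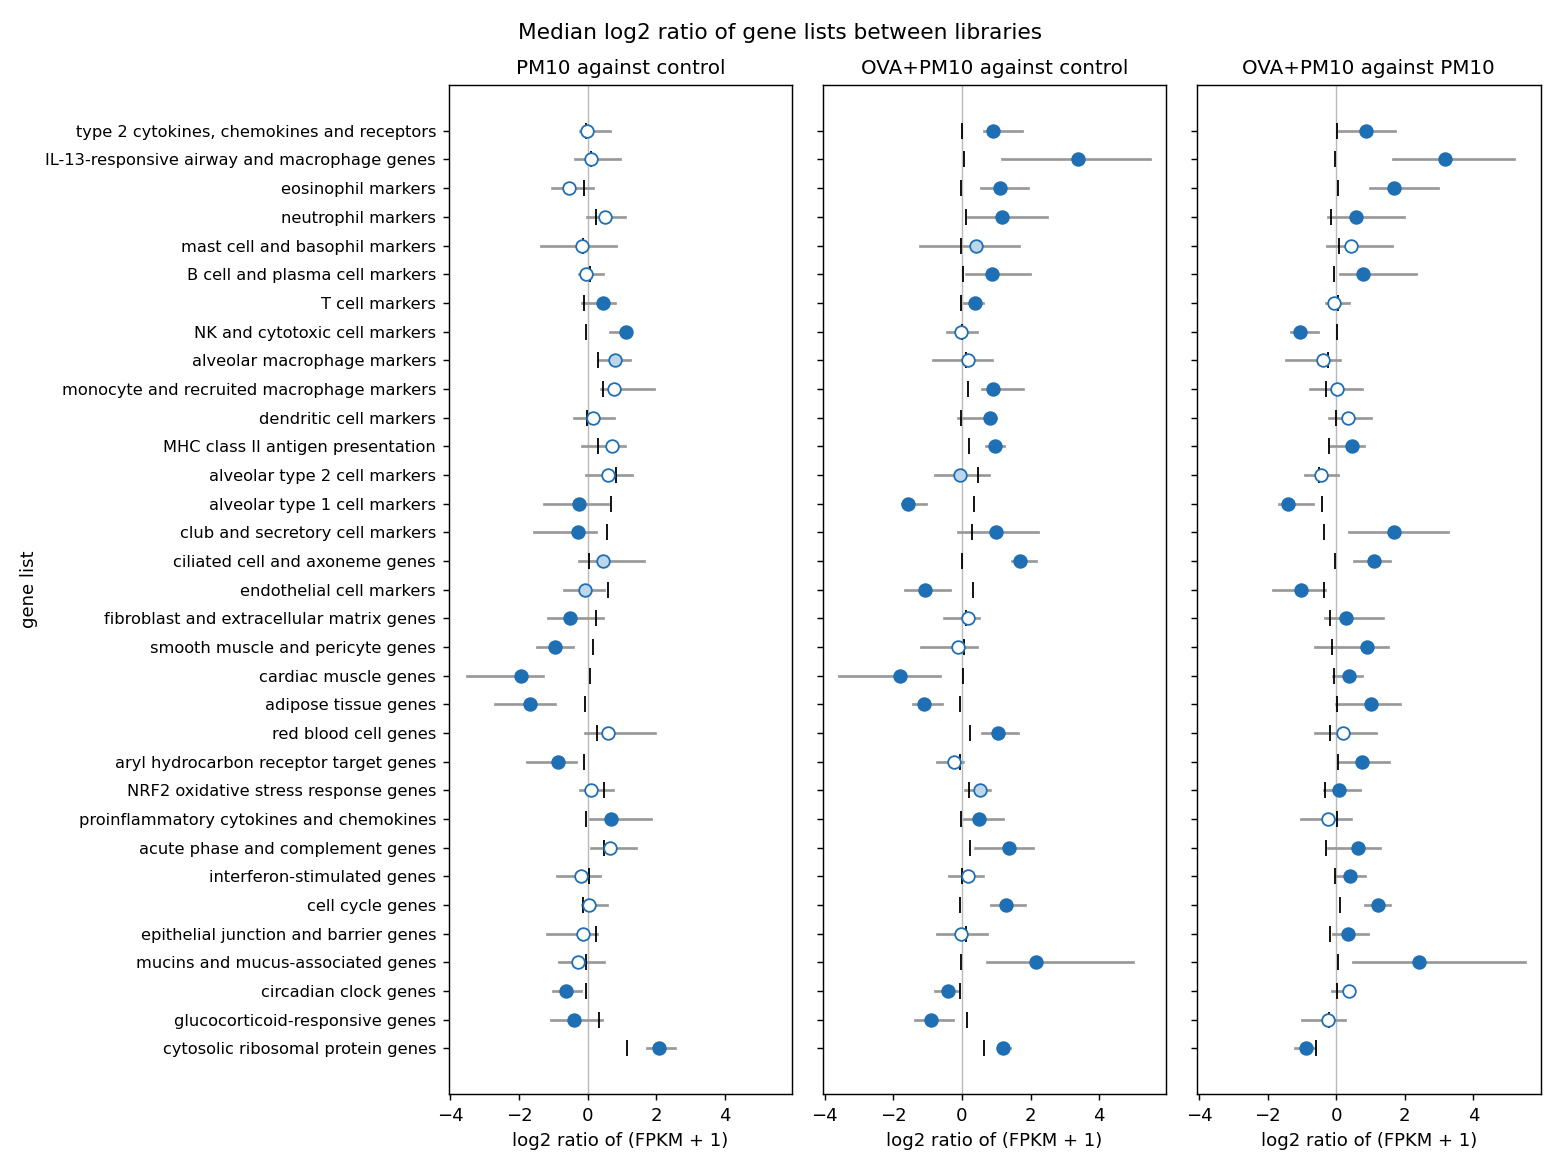
Median log2 ratio of (FPKM + 1) of each gene list that stood apart in at least 1 comparison (circles), with a grey line from the lower to the upper quartile of its members and a black tick at the median of 10000 random lists matched on expression. Dark circles stand apart with random lists matched on expression and with lists matched on length too, light circles with expression alone, and open circles with neither or with length matching alone. IL-13-responsive genes reach 3.38 in the OVA+PM10 library against control and 0.09 in the PM10 library against control. The skeletal muscle list, with a median of -5.99 in the first comparison, lies outside the axis and was left out.

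The comparison of the OVA+PM10 library with the PM10 library asked what set lungs given allergen and particles apart from lungs given particles. The mucous and type 2 genes differed here as much as against control: 21 of 25 IL-13-responsive genes were at least 2-fold higher in the OVA+PM10 library (median 3.16), as were 18 of 26 mucin and mucus-associated genes (median 2.42), 9 of 13 eosinophil markers (median 1.68) and 9 of 20 type 2 genes, with 2 lower (median 0.88). Clca1 had 5628 FPKM in the OVA+PM10 library and 2.24 FPKM in the PM10 library, Retnla 37463 and 1611 FPKM, and Muc5ac 61.8 and 0.098 FPKM. Ccl8 had 972 and 12.3 FPKM and Ccl11 95.2 and 2.67 FPKM. For Prg2, 191 FPKM stood against a value listed at 0. B cell and plasma cell markers (9 of 22 higher and 1 lower, median 0.77), cell cycle genes (22 of 35 higher and 1 lower, median 1.22) and ciliated cell genes (21 of 39 higher, median 1.10) were higher too.

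Club and secretory cell markers showed the largest median difference among lists of epithelial cell types in this comparison, with 15 of 25 at least 2-fold higher and 1 lower (median 1.67). Bpifb1 had 380 FPKM in the OVA+PM10 library and 0.619 FPKM in the PM10 library, Reg3g 330 and 1.20 FPKM, and the secretoglobin Scgb3a1 1420 and 103 FPKM. Smooth muscle genes (8 of 20 higher and 4 lower, median 0.88), fibroblast genes (14 of 36 higher and 4 lower, median 0.29) and targets of the aryl hydrocarbon receptor (6 of 16 higher and 2 lower, median 0.75) stood apart as higher, and so did adipose tissue genes (8 of 16 higher and 1 lower, median 1.01), with Cfd at 56.5 against 0.189 FPKM. Skeletal muscle genes, which both libraries held at low levels, had a median of 0.09 at the percentile of 58.3. Cardiac muscle genes stood apart as higher (5 of 24 higher and 1 lower, median 0.38), with the cardiac actin Actc1 at 60.4 against 11.04 FPKM and Myl7 at 117 against 42.1 FPKM.

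Several genes that were high in the PM10 library were lower in the OVA+PM10 library. NK and cytotoxic cell markers had 7 of 14 members at least 2-fold lower and none higher (median -1.07), or 4 lower and a median of -0.54 with the length trend removed, with Gzma at 70.5 against 374 FPKM. Of 22 alveolar macrophage markers, 9 were lower and 1 was higher, but the median of -0.38 lay at the percentile of 19.3. Within that list Fabp1 had 1.28 FPKM in the OVA+PM10 library and 32.1 FPKM in the PM10 library, and the scavenger receptor Marco 1.16 and 13.1 FPKM. Gpnmb (17.3 against 76.3 FPKM), Clec4d (10.8 against 65.8 FPKM) and Ccl3 (4.40 against 26.6 FPKM) were lower, whereas Mmp12 (90.9 against 136 FPKM), Trem2 (35.8 against 56.5 FPKM) and Ccl17 (106 against 203 FPKM) stayed within 2-fold. The proinflammatory list, with 8 of 32 lower and 5 higher, had a median of -0.23 at the percentile of 2.79. Cyp1a1 had 2.19 and 7.21 FPKM. Alveolar type 1 markers (11 of 17 lower, median -1.42) and endothelial markers (13 of 23 lower and 2 higher, median -1.02) were lower than in the PM10 library as well.

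In all, 1604 genes were at least 2-fold higher and 1220 at least 2-fold lower in the OVA+PM10 library than in the PM10 library, among 13556. The split was 3354 and 341 after scaling to the same sum, 476 and 668 with 5 FPKM added, and 290 and 111 at a 4-fold threshold. All 19 lists that stood apart as higher and all 4 as lower also did so among random lists matched on length.

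**Figure D3:**
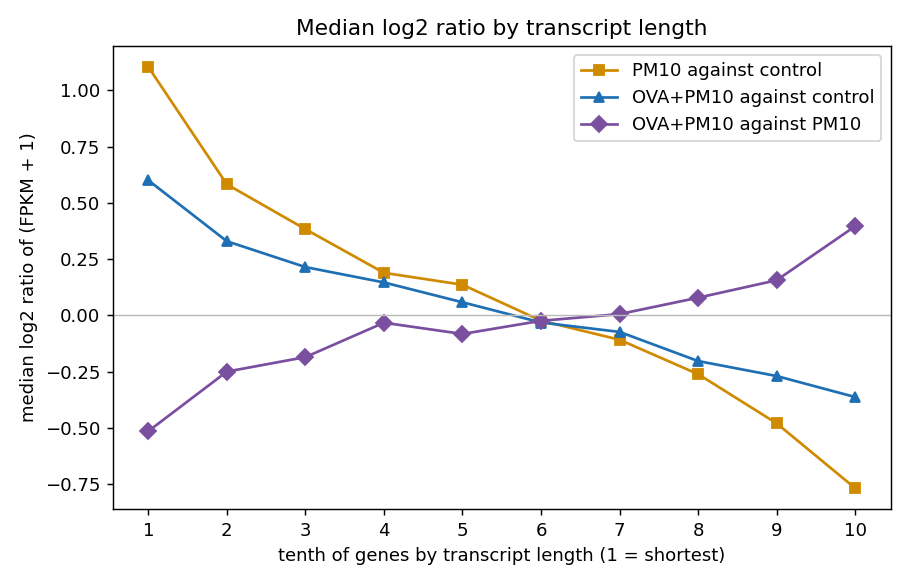
Median log2 ratio of (FPKM + 1) in 10 classes of genes by the length of their longest annotated transcript, from the shortest to the longest, for each comparison of 2 libraries. The PM10 library against control goes from 1.10 in the shortest class to -0.77 in the longest, and the OVA+PM10 library against PM10 from -0.51 to 0.40.

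The genes that differed from control overlapped between the 2 exposed libraries, which were compared with the same control library. Of the genes at least 2-fold higher than control, 569 were shared, among them Mmp12, Trem2, Saa3, Lcn2, Ccl17 and Retnla. Unchanged libraries simulated around a shared control shared 568 on average and 637 at most over 100 draws, and independent lists of these sizes would share 182. Of the genes at least 2-fold lower than control, 707 were shared, against 599 on average and 681 at most in the simulation and 162 for independent lists. For the higher genes the simulated average lay close to the observed number. For the lower genes the observed number lay above all draws. The simulated spread came from the 2 exposed libraries and may be too small for the control library. A number above all draws therefore does not show an overlap beyond the part of the shared control library. Part of the excess over independent lists may come from the shared control library, and with 1 such library that part could not be separated. Leaving out squamous epithelium and skeletal muscle genes took the number lower than control from 1907 to 1830 in the PM10 library. In the OVA+PM10 library it went from 1204 to 1127. The overlap was not recomputed without these genes, so whether it would still lie above all draws is not known.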

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

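Choices were made before the data were examined except where stated. No paired analysis was possible because each group had 1 library and no animals were matched, and for the same reason no replicate can be left out. The counts depended on several settings, and the cause was not tested for those named here. Scaling to the same sum gave 262 genes higher and 7392 lower for PM10 against control, 652 and 3560 for OVA+PM10 against control and 3354 and 341 for OVA+PM10 against PM10. Leaving out hemoglobin, immunoglobulin and cardiac muscle genes with rescaling gave, in the same order, 272 and 7275, 652 and 3553, and 3279 and 359. A 4-fold threshold gave 303 and 525, 207 and 276, and 290 and 111, and a 1.5-fold threshold 3606 and 3490, 2853 and 2451, and 3078 and 3046. With 5 FPKM added, 749 genes were lower for PM10 against control, 694 higher and 524 lower for OVA+PM10 against control, and 476 higher and 668 lower for OVA+PM10 against PM10. A filter at FPKM 5 left 1013 genes higher for OVA+PM10 against PM10. With the length trend removed, chosen after seeing the data, 1017 genes were higher for PM10 against control. The percentile of mast cell and basophil markers, OVA+PM10 against control, went from 97.54 to 4.89 with the filter at FPKM 5 and to 25.1 with the length trend removed, and that list is not described as a group.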

Other observations

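Several lists not described above stood apart. Of 18 circadian clock genes, 5 were at least 2-fold lower and 1 was higher in the PM10 library than in the control library, with a median log2 ratio of -0.64 at the percentile of 0.91, and in the OVA+PM10 library 1 was lower and 1 higher, with a median of -0.40 at the percentile of 1.16. With the length trend removed, 2 were lower and 1 higher in each. The clock repressor Nr1d1 had 62.3 FPKM in the control library, 18.5 FPKM in the PM10 library and 32.2 FPKM in the OVA+PM10 library, and the clock output factor Dbp 55.1, 15.3 and 38.8 FPKM. Of 17 glucocorticoid-responsive genes, 5 were lower and 1 was higher in the PM10 library (median -0.39, percentile 0.27), and 7 were lower and 1 was higher in the OVA+PM10 library (median -0.90, percentile below all random lists). The transcription factor Klf9 had 55.7, 4.96 and 20.8 FPKM in the same order, and Zbtb16 13.1, 1.62 and 2.56 FPKM.

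Red blood cell genes had a median of 1.04 (0.55 with the length trend removed) in the OVA+PM10 library against control, with 7 of 13 at least 2-fold higher and 1 lower at the percentile of 99.8, and the anion exchanger Slc4a1 had 11.1 FPKM there against 1.81 FPKM in the control library. Hemoglobin RNA was highest in the PM10 library, where Hba-a1 and Hba-a2 summed to 23237 FPKM, against 3469 in the control library and 7455 in the OVA+PM10 library, but the list did not stand apart there (percentile 81.7). Interferon-stimulated genes lay at the percentiles of 5.99 in the PM10 library and 93.9 in the OVA+PM10 library against control. In the PM10 library they stood apart as lower with matching on length (percentile 1.41) and with the length trend removed (0.02), such as Cxcl11 (0.099 against 3.80 FPKM), while 8 of 40 were higher and none was lower in the OVA+PM10 library than in the PM10 library, with the regulator Irf7 at 57.4 against 18.3 FPKM. Among sensory channels, Trpa1 was listed at 0 in all 3 libraries, and the list stayed at the percentiles of 38.3 and 67.2 against control.

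The tests of this part were chosen after the pattern had been seen. Short genes were higher and long genes lower in the PM10 library than in the control library, and an effective-length correction in the FPKM is not a likely source, because the 1-read step differed between short and long genes by -0.083 on the log2 scale (interval -0.13 to 0.088) where at least 0.63 was asked for. GC content is not one either, because 98.7% of the difference was left after its trend was removed. The interval of the 1-read step difference came from resampling genes and covers no variation between samples. More RNA without poly(A) tails in the PM10 library cannot be told apart from other sources. Histone genes lay at the percentile of 26.7, which met the bound set beforehand for rejecting it. A minimum of 10 reads was added after that value had been seen, and the genes had a median of about 9.52 reads in the control library and 8.24 in the PM10 library. These reads were rebuilt from the 1-read steps and transcript lengths, so that they are approximate and lie close to the minimum. RNAs that mostly carry no poly(A) tail were higher in the PM10 library, namely the ribosomal RNA precursor Rn45s (8570 FPKM, listed at 0 in both others), Rprl3 (53.0 FPKM, listed at 0 in the control library), Rmrp (212 against 17.8 FPKM) and Rpph1 (71.7 against 2.54 FPKM). A difference in RNA integrity or fragment selection could also give such a trend and was not tested.

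The test of this part was also chosen after the pattern had been seen. Squamous epithelium and skeletal muscle genes were present in the control library and nearly absent from the others, which is consistent with another tissue in the control sample, such as oesophagus or upper airway with its muscle: of 30 squamous genes not looked at before, 27 were at least 2-fold higher in the control library than in both others, against 5.00% of all genes. The squamous genes seen first summed to 12418 FPKM in the control library, 45.9 in the PM10 library and 140 in the OVA+PM10 library. A loss of such cells from the lung on exposure cannot be told apart from it, since there was 1 control library. Adipose genes were lower in both exposed libraries and could have the same origin. Whether the lower club and secretory cell markers and aryl hydrocarbon receptor targets of the PM10 library also have it was not tested. Fibroblast and smooth muscle genes did not stand apart in the OVA+PM10 library (percentiles 68.2 and 12.5). That cannot decide whether their lower values in the PM10 library have this origin, because members moved both ways in the OVA+PM10 library. Of 36 fibroblast genes there, 5 were at least 2-fold higher and 7 lower, with Col1a1 at 135 against 52.5 FPKM and Dcn at 91.8 against 246 FPKM.

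The tests of this last part were likewise chosen after the pattern had been seen. Ciliated genes were higher and alveolar type 1 and endothelial genes lower in the OVA+PM10 library than in the control library, and transcript length is not a likely source, because with matching on length the ciliated list lay at the percentile of 100 and the test of transcript length for alveolar type 1 genes gave the percentile of 0. A smaller share of alveolar tissue in the sample, acting alone, would lower type 1 and type 2 markers alike. However, their length-adjusted medians differed by 1.59 (interval 0.66 to 2.19 from resampling the marker genes). That interval covers the spread among markers in 1 pair of libraries and no variation between animals or samples. The test cannot decide on a smaller share joined with changes in type 2 genes themselves. Of 19 type 2 markers, 3 were at least 2-fold higher and 2 lower, with Chil1 at 1906 against 432 FPKM. What remains could be such a combination, or a change within the alveolar wall together with more airway in the sample or in the lung. With 1 library per group these stay open.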
